A study of Pseudomonas fluorescens with 2 samples.

How the data were processed

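The study compared 2 libraries of total RNA, 1 from wild-type *P. fluorescens* SBW25 and 1 from its hutC deletion mutant, both from exponential cultures. Per the labels' protocols, RNA was isolated with a Promega SV total RNA kit and Illumina libraries were prepared by a sequencing company. The labels also say that cultures were grown in triplicate. Whether the triplicates were pooled is not given in the sources used here, and the table has 1 value per strain. The aligner, the counting program, the strand setting, the annotation version and the genome build are not given in the sources used here.

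The deposited table has 1 row for each of 5921 protein-coding genes with its locus tag, product, positions and strand, and 1058 (17.9%) carry a gene symbol. Per the file headers, the authors deposited raw read counts, which are estimated counts that need not be whole. A remainder of 0.5 occurs in 41.8% of the wild-type values and 42.9% of the mutant values. How the fractions arose is not stated. The authors also deposited a score named normalized TPM. It equals the count divided by coding length (all lengths are multiples of 3) times 1 factor per library, to within 0.174% for genes over 50. The 2 columns do not share a total, and the values are plain TPM multiplied by 0.838 in the wild type and 1.19 in the mutant. The authors' deposited ratio and log2 ratio follow these values, with the mutant over the wild type. The deposited p-value has no stated method or adjustment, and the deposited confidence score is −log10 of it, with a sign and a cap at 1000. The columns were assigned to strains by the sample code in their headers, which matches the sample descriptions. Positions are those of the table on a single chromosome. A gene table of another strain of the species shared 0 locus tags and was not used for names.

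Changes were computed as log2 of the ratio of normalized TPM after adding a pseudocount of 1. Printed folds are ratios of normalized TPM without it. Their 95% intervals are exact (Clopper-Pearson) intervals of the share of a gene's 2 rounded counts, carried to the ratio scale. Depth was 4217233 counts in the wild type and 5131590 in the mutant. The interval of the hutC count is an exact Poisson one. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Against a count of 0, a floor of 3 counts was used. A gene counted as 2-fold different had an absolute log2 change of at least 1 and a mean normalized TPM of at least 10. Before the data were examined, the design foresaw that with 1 value per strain no test would be run and that genes past an adjusted p of 0.05 in the authors' table would be counted as theirs. The table names no adjustment, so the p-value was taken as deposited, with a threshold of 0.05, and genes past it are called here by the authors' p-value. No p-value was computed across genes.

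The 23 gene lists were also fixed before the data were examined, by symbol and product name. They cover the hut pathway, histidine biosynthesis, nitrogen regulation, urea, carbon control, the tricarboxylic acid cycle, pyoverdine, other iron genes, flagella, chemotaxis, exopolysaccharides, pili and secretion, ribosomal proteins, ribosomal and transfer RNA, respiration, heat shock, oxidative stress, general and osmotic stress, amino acid catabolism, one-carbon enzymes, GntR regulators, cyclic di-GMP and prophages. A list's median log2 change was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. This percentile describes these 2 libraries and is not a p-value. The rule for named genes, fixed likewise, took hutC, all members of the hut list and the 12 genes with the largest change in each direction. It required a mean of at least 100 where no adjusted p exists. It also took up to 4 members of each other list with the largest change among those called. The rule gave 108 genes. Genes named outside it, among them the genes with a count of 0, the other genes of the hut locus, PFLU0568 and the zinc genes, were chosen after their values were seen. Lists of genes named for zinc, copper and other metals were added after the data had been looked at.

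The steps were tested on simulated counts drawn from the means of the 5921 genes and the 2 library sizes. The size rule recovered 31.3% of genes changed 2-fold, 92.5% of those changed 3-fold and 92.4% of those changed 8-fold, and took 0% of unchanged genes. Genes set 8-fold lower can drop under the minimum mean level. The simulated counts held counting error only, with no difference between cultures and no trend with level. The 0% therefore does not carry over to the real libraries. The counting intervals covered the true fold for 94.0% to 95.5% of genes. A list of 20 genes raised 2-fold lay at percentile 100 and one of 20 unchanged genes at 30.6. The alternatives were other p thresholds, minimum levels, pseudocounts and scalings (total count, median ratio, TMM). For lists they were centring, runs of neighbouring members counted once and the hut list without hutC. Such a run held adjacent members on the same strand whose changes had the same sign. Its bounds therefore depend on the values and need not be those of an operon. Plain TPM, every setting for the 2-fold counts, the scalings of list medians and of the hut locus, centring by level and the Benjamini-Hochberg adjustment were added after the data were seen. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The scaling factors came from edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3, with no test fitted in either.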

Results

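RNA was sequenced from exponentially growing *Pseudomonas fluorescens* SBW25, a plant-associated soil bacterium, and from MU60-1, a mutant of SBW25 in which hutC is deleted. HutC is a repressor of the GntR family that is known to control the genes for histidine utilization (hut). Both strains grew in M9 minimal salts with 20 mM succinate and 10 mM histidine. Per the labels, cultures were grown in triplicate, and the deposited table holds 1 column of read counts per strain, so each strain had 1 library. The table lists 5921 protein-coding genes. The wild-type library held 4217233 gene counts with a median of 200 per gene, and the mutant library held 5131590 with a median of 174.5. Of the genes, 5908 in the wild type and 5802 in the mutant had at least 10 counts. Levels are given as the authors' normalized TPM, and folds are ratios of these values with 95% intervals that cover counting error only. With 1 library per strain, no difference below has a replicate check.

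The comparison of the mutant with its parent asked which genes depend on the HutC repressor. The deleted gene itself was read first, as a check of the labels. hutC (PFLU0359, chromosome positions 396119 to 396868, forward strand) had 651.5 counts in the wild-type library, with an exact Poisson interval of 603 to 704, and a level of 132.2. In the mutant library it had 18.5 counts, with an interval of 10.7 to 28.4, and a level of 4.8. The mutant level was 3.63% of the wild-type level, or 27.5-fold lower (18.1 to 48.9). The deleted gene thus went with the labels. The table gives counts per whole gene, so the place of the remaining reads within hutC is not known.

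The genes around hutC did not move as a block. PFLU0358, the N-formimino-L-glutamate deiminase that lies beside hutC on the reverse strand, was 3.67-fold higher in the mutant library (3.51 to 3.85), at 989.8 against 269.4. PFLU0360, a hypothetical protein whose start overlaps the end of hutC, was 2.26-fold higher (1.95 to 2.62), at 175.5 against 77.6. hutU, which encodes urocanate hydratase, the enzyme of the second step of histidine breakdown, was 1.62-fold higher (1.59 to 1.65), at 3219.9 against 1984.7. The histidine transporter genes that follow were lower in the mutant library. The substrate-binding protein gene PFLU0363 was 2.79-fold lower (2.69 to 2.89), at 786.1 against 2193.5, and the ATP-binding protein gene PFLU0365 was 2.26-fold lower (2.18 to 2.34), at 953.7 against 2155.9. The membrane protein genes PFLU0362 and PFLU0364 and the permease gene PFLU0368 were 1.62-fold, 1.57-fold and 1.58-fold lower, and PFLU0366, a putative histidine lyase, was 1.78-fold lower. hutH, which encodes the histidine ammonia-lyase of the first step, had 294.5 in the wild type and 285.8 in the mutant, with an interval for the fold that includes 1 (0.976 to 1.09 as fold lower). The imidazolonepropionase gene PFLU0369 had 509.1 and 599.2, and the last gene, PFLU0370, had 562.9 and 537.5. Across the 13 genes from PFLU0358 to PFLU0370 (394646 to 410687), the share of all gene counts was 1.76% in the wild type and 1.14% in the mutant. This span was chosen after the values were seen. Shares of all gene counts compare the libraries by total count, not by the deposited scaling of the folds above. The median of all genes also lay lower by total count, at −0.59 on the log2 scale. By total count and by plain TPM the log2 change of hutU was 0.08 and 0.19 in place of 0.70, and that of PFLU0369 turned from 0.23 to −0.38 and −0.28. That of hutH was −0.65 and −0.55 in place of −0.04, and that of PFLU0370 was −0.68 and −0.58 in place of −0.07. PFLU0358 stayed higher by total count, at 1.26 in place of 1.87, as did PFLU0360, at 0.56 in place of 1.17. The transporter genes and PFLU0366 stayed lower, as they had to, since both scalings lower every gene.

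**Figure D1:**
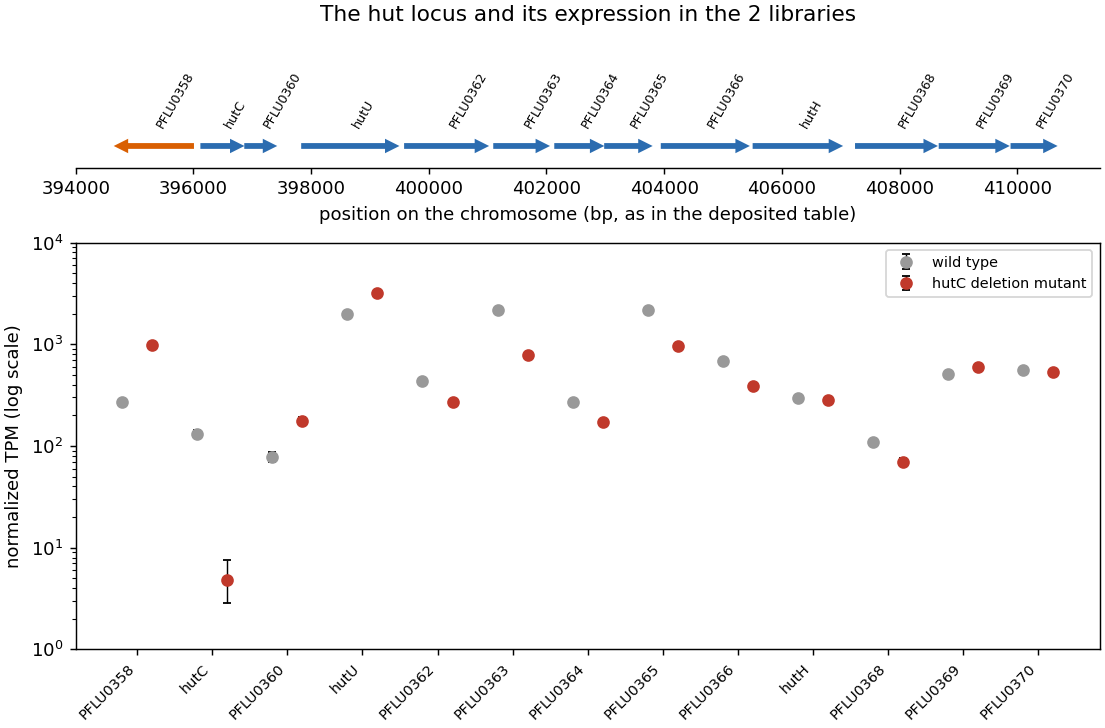
Map of the hut locus (top, positions in bp, arrows show strand) and the normalized TPM of each gene on a log scale (bottom) in the wild-type library (grey) and the hutC deletion library (red), with bars for 95% counting intervals. By this scaling hutC lies at 132.2 and 4.8, PFLU0358 and hutU lie higher in the mutant, and the transporter genes PFLU0362 to PFLU0365 lie lower; by total count the log2 change of hutU was 0.08.

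The list of hut pathway genes that was fixed by name before the data were examined held 8 members, 5 of them in this span. It missed the deiminase gene PFLU0358, PFLU0366 and the transporter genes PFLU0362, PFLU0364, PFLU0365 and PFLU0368. Of the 13 genes of the span, 3 were higher and 7 lower by the deposited p-values. In the authors' deposited table, 1 of the 8 had a p-value under 0.05 as higher (hutU), 2 as lower (hutC and PFLU0363) and 5 in neither direction. PFLU0430, a second putative histidine ammonia-lyase, had 20.4 in the wild type and 14.1 in the mutant. The putative histidine permease genes PFLU4763 and PFLU4764 had 17.0 and 19.7, and 22.0 and 11.7. The median log2 change of the list was −0.27, at percentile 9.53 among 10000 random lists matched on level, and it was −0.04 without hutC and 0.096 over the 4 members with a mean level of at least 100.

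Over the whole genome, genes for making and taking up the siderophore pyoverdine stood far higher in the mutant library than in the wild type. Pyoverdine is an iron-binding compound that fluorescent pseudomonads secrete. pvdG, a putative thioesterase gene of pyoverdine synthesis, was 262-fold higher (193 to 381), at 1940.2 against 7.4. fpvA, the gene for the ferripyoverdine receptor, was 121-fold higher (113 to 130), at 6276.7 against 51.9, and fumC, a fumarate hydratase gene, was 41.4-fold higher (39.8 to 43.2). At the other end, bfr1, which encodes the iron-storage protein bacterioferritin, was 22.3-fold lower (17.8 to 28.2), at 32.5 against 723.4. By size alone, on the log2 scale with a pseudocount of 1, 759 genes were at least 2-fold higher and 546 at least 2-fold lower, among genes with a mean level of at least 10. On the same scale, 104 genes were at least 8-fold higher and 20 at least 8-fold lower. The authors' deposited table gives a p-value under 0.05 to 2193 genes, 1303 of them higher and 890 lower, from these 2 libraries, so it compares the libraries and not the strains. The table names neither its test nor an adjustment, and it gives short genes a p-value under 0.05 at lower read counts than long ones. The direction counts rest on the scaling. When the libraries were scaled by their total counts, the median gene lay at −0.59 on the log2 scale, and 372 genes were at least 2-fold higher and 1429 lower. With plain TPM the median gene lay at −0.49, with 414 higher and 1239 lower. Changes below are relative to the deposited scaling, under which the median gene lay at 0. Genes at low levels also lay lower in the mutant library, with a median log2 change of −0.84 over the 593 genes lowest in mean level (median 7.9) and of 0.41 over the 592 highest (median 614.9).

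**Figure D2:**
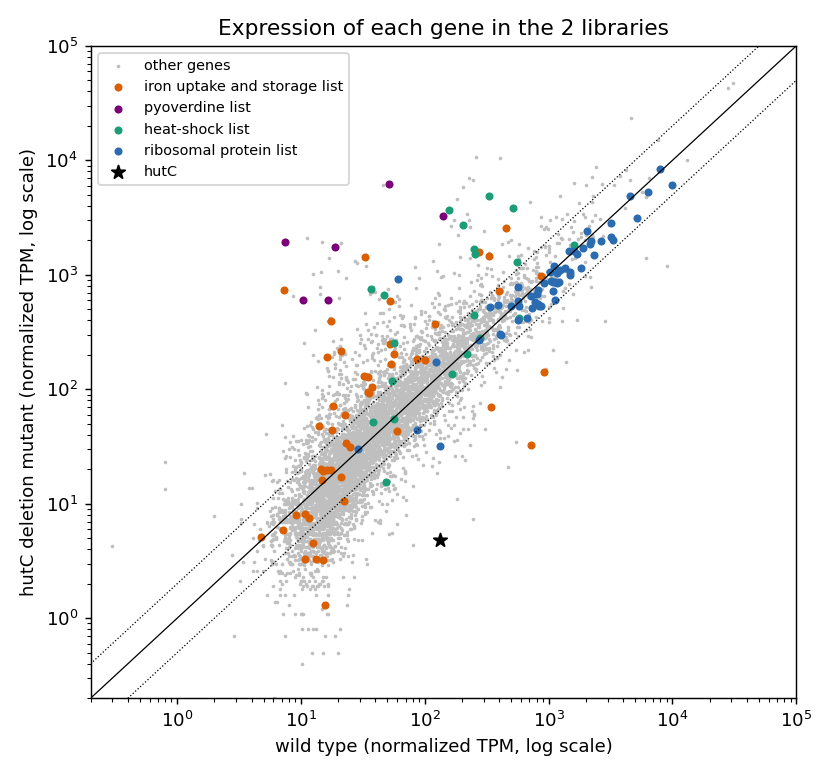
Normalized TPM of each gene in the wild-type library (x axis) and the hutC deletion library (y axis), both on log scales, for genes with values above 0. The solid line marks equal values, the dotted lines mark 2-fold differences, and colours mark gene lists. Pyoverdine genes lie far above the line, at up to 262-fold for pvdG, and hutC lies below it at 27.5-fold.

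The 12 genes that stood highest in the mutant by the fixed rule (mean level of at least 100) included pvdG and fpvA. Among the others, the diaminobutyrate-2-oxoglutarate aminotransferase gene PFLU4378 was 131-fold higher, its neighbour PFLU4377, a hypothetical protein gene, 134-fold, and the putative L-ornithine 5-monooxygenase gene PFLU3975, of a kind used in siderophore synthesis, 83.7-fold. The peptide synthase gene PFLU6137 was 81-fold higher (76.2 to 86.1). PFLU5135, a putative aminotransferase gene, was 187-fold higher, the ABC transporter gene PFLU2546 beside fpvA 74.4-fold, and the hypothetical protein genes PFLU2548 and PFLU6093 89.2-fold and 72.9-fold. Among the 12 that stood lowest in the mutant, which include bfr1, bfr2 and gltB, the hypothetical protein gene PFLU1419 stood first, at 33.6-fold lower (21.9 to 59). The putative glutamine-binding protein gene PFLU4268 was 22.4-fold lower and the neighbouring putative dioxygenase gene PFLU4269 was 8.86-fold lower. The pyrimidine-degrading dihydropyrimidine dehydrogenase gene PFLU3944 was 15.5-fold lower, and the phenylhydantoinase gene PFLU3942 was 8.04-fold lower. ilvH and PFLU5220, for the subunits of acetolactate synthase in branched-chain amino acid synthesis, were 7.62-fold and 7.2-fold lower, ilvH from 9090.7 to 1193.3. The hypothetical protein genes PFLU1721 and PFLU5298 were 7.61-fold and 6.81-fold lower. Putative lipoprotein gene PFLU2861 and hypothetical protein gene PFLU4138 had 29.5 and 49 counts in the wild type and 0 in the mutant, and were at least 7.82-fold and at least 13.0-fold lower against a floor of 3 counts.

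All 6 members of the pyoverdine list were at least 2-fold higher in the mutant library, with a median log2 change of 6.10 at percentile 100. They stayed so under each scaling tried, as they had to. Their smallest log2 change was 4.53, and the largest shift by a scaling was −0.614. Besides pvdG and fpvA, pvdI, which encodes a peptide synthase, was 57.8-fold higher (54.1 to 61.6) and the synthetase F gene PFLU2547 was 93.8-fold higher. The share of gene counts in this list was 0.0885% in the wild type and 3.64% in the mutant. In the list of other iron and haem uptake and storage genes, 23 of 49 were at least 2-fold higher, 9 at least 2-fold lower and 17 within 2-fold. Its median was 0.84, at percentile 100, and was 0.23 by total count, 0.33 by plain TPM and 0.48 with runs of neighbouring members counted once. By the deposited p-values 25 were higher, 6 lower and 18 neither. The ferric alcaligin siderophore receptor gene PFLU2688 was 102-fold higher (83.9 to 124), and the TonB-dependent receptor genes PFLU0757 and PFLU1087, which serve uptake across the outer membrane, were 43.8-fold and 22.4-fold higher. The lower members included the bacterioferritin genes, with bfr2 6.55-fold lower (5.85 to 7.34), at 141.1 against 923.8.

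Chaperone and heat-shock protease genes were also higher in the mutant library. Of 20 members, 11 were at least 2-fold higher and 1 at least 2-fold lower, and the median log2 change of 1.16 lay at percentile 99.9, and the median was 0.55 by total count and 0.65 by plain TPM. By the deposited p-values 13 were higher, 2 lower and 5 neither. dnaK was 14.9-fold higher (14.4 to 15.3), at 4866 against 327.4, htpG 20.4-fold, the protease gene hslU 14.2-fold, and the small heat shock protein gene PFLU4295 23.5-fold. Of the 14 oxidative stress genes, 2 were at least 2-fold higher and 1 lower, 6 being higher and 1 lower by the deposited p-values. sodA, for a superoxide dismutase, was 25.6-fold higher (23.8 to 27.6), at 4636.9 against 181.2, while the other putative superoxide dismutase gene PFLU4855 was 2.62-fold lower. The alkyl hydroperoxide reductase gene PFLU2989 was 2.39-fold higher and the regulator gene ohrR 1.92-fold. The median of this list was 0.31, at percentile 71.8, and lay below 0 by total count and by plain TPM. The 24 general stress and osmotic genes went both ways, with 9 higher and 6 lower by the deposited p-values and 2 and 4 by size. osmC was 3.28-fold higher, and the glycine betaine transport genes PFLU1812 and PFLU5681 and the trehalose-6-phosphate hydrolase gene PFLU5039 were 4.93-fold, 2.69-fold and 3.91-fold lower. The median of 0.30, at percentile 69.2, turned below 0 by total count and by plain TPM.

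The lists for the tricarboxylic acid cycle and for nitrogen regulation split in direction, while all called urea and urease genes were lower. Of the 33 members of the list for the tricarboxylic acid cycle and C4-dicarboxylate uptake, 14 were higher and 9 lower by the deposited p-values, and 6 and 4 by size. Besides fumC, the members with the largest differences were the C4-dicarboxylate transporter genes PFLU4717 (DctA) and PFLU3953 and the methylcitrate synthase gene PFLU4631. PFLU4717 was 3.77-fold lower (3.52 to 4.04), and PFLU3953 was 3.57-fold lower at low levels, 3.7 against 13.2. PFLU4631, for an enzyme of propionate breakdown and not of the cycle, was 3.39-fold higher. The median was 0.15, at percentile 31.5, and lay below 0 by total count and by plain TPM. It lay at −0.19 with runs of neighbouring members counted once and at −0.071 when centred by level. hfq, for an RNA-binding protein of carbon catabolite control and the only member of that list, was 2.97-fold higher (2.81 to 3.15). In nitrogen regulation and ammonium assimilation, 5 of 22 genes were higher and 4 lower by the deposited p-values, 2 and 5 by size. gltB and gltD, for glutamate synthase, were 7.2-fold (6.7 to 7.8) and 4.35-fold lower, and the low-level nitrite reductase genes PFLU3424 and PFLU3425 were 7-fold and 4.84-fold lower. The median of 0.03, at percentile 45.7, turned below 0 by total count, by plain TPM and under both kinds of centring. Of 7 urea and urease genes, 4 were lower and 0 higher by the deposited p-values, with ureE 5.04-fold, ureG 4.38-fold, ureB 3.41-fold and ureC 1.43-fold lower and a median of −0.75 at percentile 6.81, where matched random lists ran from −0.92 to 0.46.

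Of the 24 genes for catabolism of other amino acids, 11 were higher and 3 lower by the deposited p-values, 4 and 2 by size. The 4-aminobutyrate aminotransferase gene PFLU4036 was 7.85-fold higher (6.59 to 9.44), the arginine N-succinyltransferase gene PFLU4756 4.95-fold and dadA 3.7-fold, and the 4-hydroxyphenylpyruvate dioxygenase gene PFLU2997, of tyrosine breakdown, was 4.57-fold lower. The median of 0.60, at percentile 99.8, was −0.01 by total count. Of 13 histidine biosynthesis genes, 2 were higher and 4 lower by the deposited p-values and 1 was at least 2-fold higher. That gene was the hisI copy PFLU6092, 23.8-fold higher (16.3 to 35.7), at 252.4 against 10.6, and reads shared with the other hisI copy cannot be excluded. hisC was 1.87-fold higher, and hisD and hisZ were 1.92-fold and 1.69-fold lower, with a list median of −0.18 at percentile 3.72. Of 22 formate and one-carbon genes, 2 were higher and 4 lower by the deposited p-values, and 6 were at least 2-fold lower. folD was 6.91-fold lower, glyA 4-fold, and the sarcosine oxidase genes soxD and soxA 2.8-fold and 2.44-fold, from levels of 15.9 to 41.4 in the wild type. The median was −0.45, at percentile 12.8 of random lists that ran from −0.62 to 0.18, and the 2 members with a mean level of at least 100 had a median of 0.67.

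Ribosomal protein genes lay a little lower as a group. Of 57 members, 39 were lower and 7 higher by the deposited p-values, and 55 lay within 2-fold. Their median of −0.25 lay at percentile 0 of the random lists, whose medians ran from 0.25 to 0.78 (central 95%). It lay below 0 under each scaling, which decides nothing, because the other scalings lower every gene. rpsT was 1.87-fold lower (1.73 to 2.03) and rpmE 1.95-fold lower. The member at least 2-fold higher was rpmE2, an alternative form of protein L31, at 15-fold (12.3 to 18.3), and rimO, which modifies a ribosomal protein and is not one, was 4.15-fold lower. The list meant for ribosomal and transfer RNA caught no RNA gene but 5 genes for enzymes that modify these RNAs, 2 of them lower by the deposited p-values, with dusB 3.66-fold and mnmA 1.8-fold lower and a median of −0.40 at percentile 7.75. Of 32 respiration and ATP synthase genes, 11 were lower and 6 higher by the deposited p-values, and 6 were at least 2-fold lower. The NADH dehydrogenase subunit C/D gene PFLU3820 was 3-fold lower (2.74 to 3.27), the cytochrome oxidase genes PFLU4556 and PFLU4555 2.71-fold and 2.64-fold, and petA 2.21-fold. The median of this list was −0.11, at percentile 0.77. It too lay below 0 under each scaling, which likewise decides nothing.

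Of 42 flagellar genes, 17 were higher and 3 lower by the deposited p-values, and 4 were at least 2-fold higher, namely flgE at 2.47-fold (2.39 to 2.55), the flagellin gene PFLU4448 at 2.29-fold, flgG at 2.1-fold and fliJ at 2.08-fold. The median of 0.28, at percentile 48.2, was −0.34 by total count, −0.23 by plain TPM and −0.11 when centred by level. Of 79 chemotaxis genes, 13 were higher and 10 lower by the deposited p-values, 6 and 8 by size, with a median of −0.03 at percentile 32.5 that was 0.015 over members with a mean level of at least 10. The receptor gene PFLU5092 was 8.72-fold higher (7.47 to 10.3) and the response regulator gene PFLU5095 5.19-fold higher, while the receptor genes PFLU2262 and PFLU4792 were 4.18-fold and 4.12-fold lower. Of 39 exopolysaccharide genes, 9 were higher and 10 lower by the deposited p-values, 4 and 6 by size. The cellulose genes wssA, wssB and wssH were 3.14-fold, 3.4-fold (3.16 to 3.67) and 3.32-fold lower, and algP1, an alginate regulator gene, was 2.77-fold higher. The median of 0.19, at percentile 86.5, turned below 0 by total count and by plain TPM. Among 30 genes for type IV pili and type III and VI secretion, 6 were lower and 0 higher by the deposited p-values, with a median of −0.54 at percentile 7.95. The type III secretion genes rspP, rspB, rspV and rscQAB were 6.21-fold, 6.61-fold, 4.96-fold and 3.73-fold lower, from levels of 20.5, 11.9, 13.4 and 17.9 in the wild type, and random lists matched on level had medians from −0.63 to 0.05.

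In the remaining lists the members went both ways. Of 38 genes for GntR-family regulators, the family of HutC, 5 were higher and 8 lower by the deposited p-values, 3 and 6 by size. After hutC, the members with the largest differences were PFLU3295, PFLU3460 and PFLU1071, at 3.9-fold, 3.75-fold and 3.26-fold lower. Their wild-type levels were 16, 21 and 51.9. The list median was 0.03 at percentile 48.2, turning below 0 by total count, by plain TPM and under both kinds of centring. Of 28 cyclic di-GMP enzyme genes, 2 were higher and 6 lower by the deposited p-values, with PFLU3650 and PFLU3540 at 2.6-fold and 2.32-fold lower and PFLU1349 and PFLU4198 at 2.14-fold and 2.01-fold higher, and a median of −0.27 at percentile 29. Of 47 prophage and bacteriocin genes, 13 were higher and 2 lower by the deposited p-values, 8 and 3 by size. The phage protein genes PFLU2832, PFLU4584 and PFLU1180 were 4.54-fold (3.8 to 5.43), 2.84-fold and 2.81-fold higher. The phage tail gene PFLU2891 was 8.74-fold lower (3.75 to 24.3) at low levels, 1.9 against 16.6, with a mean of 9.25. The median of 0.27, at percentile 99.7, was −0.32 by total count and −0.22 by plain TPM.

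**Figure D3:**
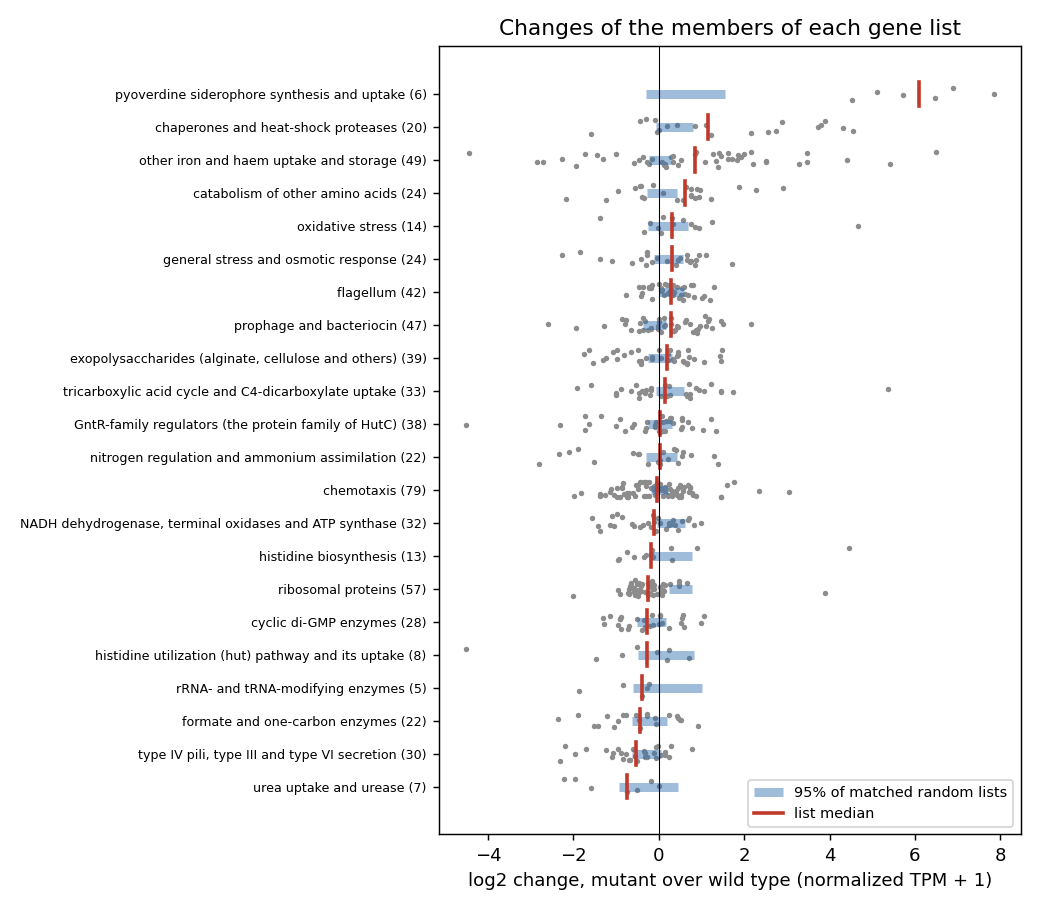
Log2 change (mutant over wild type, normalized TPM plus 1) of each member (grey points) of the gene lists with at least 3 members, with the list median (red line) and the central 95% of medians of random lists matched on level (blue bar). The pyoverdine median of 6.10 and the heat-shock median of 1.16 lie above their bars, and the ribosomal protein median of −0.25 lies below its bar.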

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

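Plain TPM, every setting for the 2-fold counts, the scalings of list medians, centring by level and the adjustment were chosen after the data were seen; the other settings were chosen before. All 103 named genes called by the deposited p-value kept their sign under both other pseudocounts and all 4 other scalings, which decided nothing. A pseudocount added to both values cannot turn a sign. The other scalings lower every gene, with a largest log2 shift of −0.614, and the smallest rise among the called named genes was 0.698 (hutU). Of the uncalled named genes, 2 changed sign by total count and plain TPM. The 2193 called genes became 1240 with an absolute log2 change of at least 1 (749 higher, 491 lower), 1101 with a mean level of at least 100 (790 higher, 311 lower) and 1804 with Benjamini-Hochberg adjustment. At a p under 0.01 the 890 lower genes became 584. Of 759 genes 2-fold higher, 398 were left at a mean of at least 100, 372 by total count and 414 by plain TPM. The 546 genes 2-fold lower became 78 at a mean of at least 100, 361 with a pseudocount of 5, 1429 by total count and 1239 by plain TPM. hutC moved from −4.52 to −3.81 with a pseudocount of 5. Filters leave fewer genes, and a larger pseudocount shrinks low levels, by construction. Members with a mean of at least 100 gave medians of 2.001 (iron, 20 members), −0.044 (pili and secretion, 4), 1.01 (prophage, 8) and, reversed, 0.67 (one-carbon, 2); the cause was not tested. Scaling by total count or plain TPM lowers each list by a similar amount, and gave medians of −0.79 and −0.69 (histidine biosynthesis), −0.46 and −0.36 (tricarboxylic acid cycle), −0.64 and −0.54 (chemotaxis), −1.09 and −0.997 (pili and secretion), −0.86 and −0.76 (ribosomal proteins), −0.71 and −0.61 (respiration), −0.29 and −0.19 (oxidative stress), −0.53 and −0.44 (GntR), −0.85 and −0.76 (cyclic di-GMP) and −0.32 and −0.22 (prophage). The same scalings gave −0.56 and −0.46 (nitrogen), −0.30 and −0.20 (general stress), −1.01 and −0.92 (one-carbon), 0.23 and 0.33 (iron, 0.48 with runs of neighbouring members counted once) and 0.55 and 0.65 (heat shock). The flagellar median of 0.28 reversed to −0.34 by total count, −0.23 by plain TPM and −0.11 when centred by level. It was 0.030 with runs of neighbouring members counted once. Ribosomal proteins centred by level lay at −0.66. List medians that changed sign otherwise were those of the tricarboxylic acid cycle (−0.19 with runs of neighbouring members counted once, −0.071 centred by level), nitrogen (−0.039 centred on all genes with a mean of at least 10, −0.042 by level), GntR (−0.036 and −0.13), chemotaxis (0.015 and 0.10 with means of at least 10 and 100) and hut (0.096 at 100). Total count and plain TPM also turned exopolysaccharides (−0.41 and −0.31), and total count turned amino acid catabolism (−0.0056). No paired analysis was possible because there is 1 library per strain. For the same reason replicate filters, edgeR and DESeq2 tests, leaving out a replicate and the camera and fry tests were not run, and the hut list held no hutD to leave out.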

Other observations

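The tests of swapped labels, of a shared factor, of another culture difference and of the deposited p-values were chosen after the values were seen, and the other tests before. Beyond the lists, several runs of neighbouring genes differed together, and they were picked after their values were seen. The 13 genes from PFLU6083 to PFLU6094 (6660761 to 6671500) were all at least 2-fold higher in the mutant library, with a median log2 change of 4.21 under the deposited scaling. They include the cation transporter genes PFLU6089 and PFLU6090, at 10.8-fold and 4.14-fold, the periplasmic protein gene PFLU6091 at 44.8-fold (38.2 to 52.3), the GTP cyclohydrolase gene PFLU6088 at 18.9-fold, the second hisI copy and the dihydroorotase gene PFLU6094 at 30.9-fold. fumC and sodA lie in a run of 5 genes, PFLU0873 to PFLU0877 (985469 to 989229), all higher, with a median of 4.82, and the share of gene counts in this run was 0.108% in the wild type and 2.36% in the mutant.

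Other runs were lower in the mutant library. In the wss operon (327255 to 342812), which makes the cellulose of SBW25 biofilms, 6 of 10 genes were at least 2-fold lower and 9 were lower by the deposited p-values, while wssG had 36.1 in both libraries. The ketol-acid reductoisomerase gene PFLU5218, ilvH and PFLU5220 (5725506 to 5728788) held 2.44% of gene counts in the wild type and 0.275% in the mutant. The hydantoinase run PFLU3942 to PFLU3944 had a median of −3.92, and the 6 genes PFLU4265 to PFLU4270, with the acetylornithine deacetylase gene PFLU4265 at 6.04-fold lower, had a median of −3.08.

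All 6 pyoverdine genes and 23 of 49 other iron genes were at least 2-fold higher in the mutant library, and 9 of the 49, among them bfr1, bfr2 and the putative bacterioferritin gene PFLU0568, at least 2-fold lower. A swap of the 2 labels is argued against by hutC, 27.5-fold lower in the library labelled as the deletion. A factor shared by every gene, as when a few abundant genes take up reads, is argued against by the medians of the pyoverdine and iron lists, both at percentile 100 of random lists matched on level, which such a factor leaves in place; directions under total count decided nothing, since that shift could turn 0 of the 37 called members. Lower availability of other metals stays open. Genes named for zinc, a list added after the data had been looked at, had a median of −0.47. This lay under the bound of 0.5 set against that explanation before the list was read. The bound was a poor one, because the 11 members ran from −1.05 to 1.27 and mix transport genes with efflux genes and zinc-binding dehydrogenases. By the deposited p-values 3 members were higher, 1 lower and 7 neither. The 3 higher ones are neighbours: znuC (205.5 against 84.5), PFLU0075 (153.7 against 70.5) and PFLU0076 (191 against 108.7). The transport genes znuB (43.9 against 37.8) and PFLU4616 (131.7 against 117.8) were not called. The list also leaves out the cation transporter genes PFLU6089 and PFLU6090, 10.8-fold and 4.14-fold higher, whose products name no metal. Both lie in the run PFLU6083 to PFLU6094, whose 13 genes were all at least 2-fold higher and all outside the list. The cause of that rise was not tested. An effect of the hutC genotype and another difference between the cultures, such as iron carry-over or growth stage, cannot be told apart with 1 library per strain, and either may underlie the pattern.

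Genes read at a low level lay lower in the mutant library, and gene length did not account for this, since the gap in median log2 change between the 592 genes highest and the 593 lowest in level was at least 1.14 in each of 4 classes by length, against 1.25 over all. Uniform background reads, more of them in the wild-type library, may contribute. Of the 593 lowest genes, 3.88% had a wild-type level below the 4.8 by which they were offset at the median, where background would allow at most 5%. The test is a weak one, since these genes were chosen by mean level, and a biological difference between strains was not tested.

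The deposited p-values followed normalized TPM more closely than read counts. A counting test on length-normalized values is a candidate explanation: a two-sided binomial test on rounded normalized TPM differed from the deposited p by a median of 0.169 in log10 units over 5146 genes, and one on counts by 3.11. Among genes with 100 to 300 counts in all and at least a 2-fold difference, 79 of 79 with coding lengths under 500 bp had a deposited p under 0.05, against 14 of 52 over 1500 bp. A total of 137 genes were 2-fold different with a deposited p not under 0.05, although their counting intervals exclude 1, and 124 of them were lower in the mutant.

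In lists also added after the data had been looked at, genes named for copper (8, median 0.01) and for other metals (6, median −0.51) had percentiles of 60.2 and 20.5 among matched random lists.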
